A study of Mus musculus with 86 samples.

How the data were processed

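Transcripts were measured by GeoMx digital spatial profiling in sections of mouse back skin. In this method, probes bound to RNA carry barcodes. Ultraviolet light releases the barcodes from chosen areas of a section, called segments, and they are counted by sequencing. Per the labels' protocols, female C57BL/6 mice of 12 to 16 weeks received 1 UVB exposure of 500 mJ/cm2 (290 to 320 nm), and biopsies were taken at 0, 6 and 24 h. Regions of interest were divided by staining into PanCK-positive areas (pan-cytokeratin, a marker of epithelial cells) and CD45-positive areas (a marker of leukocytes), per the labels' protocols. The labels place the 85 segments in 5 compartments: PanCK epidermis, CD45 epidermis, PanCK deep dermis, CD45 deep dermis and CD45 adipose. They name 3 mice (208, 210 and 219), all under the same scan number, so that time is not confounded with the scan. Counts of a no template control entered no fit and are only set beside those of the tissue segments.

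The deposited values are counts, 1 whole number per probe identifier and segment, made by the authors with GeoMx NGS Pipeline 2.3.3.10, per the file headers. No normalization of these counts is recorded, and none was found in the values. The total count of a segment was 1.13% of its aligned reads in the median (0.88 to 1.62%), so the counts were taken as molecules left after removal of duplicate reads, which the headers do not state in words. In all, 20175 probes are listed in at least 1 segment. The name of the probe panel, the aligner and the genome build are not given in the sources used here. The deposited count files do not pair probe identifiers with genes, so no gene is named, and the gene list tests chosen before the data were examined were not run. Identifiers stand in the text as the deposited values give them.

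Counts were summed over the segments of each mouse, compartment and time, which gave 44 sums, with 3 mice in every group except adipose at 6 h (2 mice). The mouse was the replicate and the segments were not. Each compartment was fitted alone over its 3 times with the mouse as a block, in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM scaling, filterByExpr at its minimum count of 10 and the quasi-likelihood F test. Probes with a Benjamini-Hochberg adjusted p under 0.05 are called. The 5 comparisons of compartments used the 0 h sums in 1 fit, again with the mouse as a block. Differences between time courses were tested by the 2 compartment-by-time coefficients together, with the biopsy as a block. The pairing comes from the labels, which give the same mouse number at every time; whether each animal was biopsied serially is not stated in more words. As a check, deviations from the group means, compared at different times, correlated across probes with a median r of 0.0165, 0.00973, 0.143, 0.153 and 0.241 within a mouse in PanCK epidermis, CD45 epidermis, PanCK deep dermis, CD45 deep dermis and adipose. Between mice the medians were 0.000333, -0.00773, -0.0389, -0.0691 and -0.102. Deviations from the mean of the same few mice sum to 0, which pulls the between-mouse values opposite to the within-mouse ones. They are therefore not a separate reference. Without the replicate block, 1264 probes in place of 1279 were called in PanCK epidermis at 24 h against 0 h.

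Named probes followed a rule: the 2 rising and the 2 falling probes with the smallest p in the UVB comparison with the most calls, followed through all compartments. Behind counts of 5 or fewer calls, the probes with the smallest p are also named, at most 2 that rose and 2 that fell in a comparison, and were chosen after their values were seen. Levels are CPM, counts scaled to the total of their sum, with the SD over mice. Fold changes come with a standard error derived from the fold change and the F statistic of edgeR's fit. The fit assumes that a mouse adds the same log2 shift at each time. The share of counts on the 100 most abundant probes was taken in each sum. The share on 5000 scarce probes, called floor probes here, was taken for the probes with the lowest mean share in deep dermis and adipose. Whether these are negative control probes is not given in the sources used here. Shares at 24 h and 0 h were compared by an exact two-sided permutation within mice.

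Groups, fits, the rule for named probes and 10 alternatives were fixed before the data were examined. These alternatives are DESeq2's size factors, upper quartile scaling, no filter, the test of DESeq2 1.42.0, limma on the mean of log2(CPM + 1) over the segments of each mouse, omission of shallow segments, omission of the block, and omission of each mouse in turn. Shallow segments are those under 11890.8 counts, of which there were 2. Scaling to the floor probes, and a filter that keeps probes above their level, were added after seeing the data. Python 3 with scipy, pandas and matplotlib served for reading, intervals and plots.

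Total counts per segment ranged from 4244 to 256121. Intervals for shares of counts are 95% Wilson intervals and intervals for ratios of counts are 95% exact binomial intervals. Both cover counting error only. The steps were tested on simulated counts with 200 changed probes, drawn from the real means and totals. With the mean log values, 37% of 4-fold changes were called in PanCK epidermis. With edgeR, 71% of 4-fold and 12% of 2-fold changes were called in PanCK epidermis, 88% and 33% in CD45 epidermis, 82% and 33% in PanCK deep dermis, 81% and 22% in CD45 deep dermis, and 75% and 29% in adipose. For differences between time courses, 33 to 47% of 4-fold changes were called. In these simulated counts edgeR also called 2 to 9 unchanged probes per compartment at 24 h against 0 h, and 0 at 6 h against 0 h, where no probe had been changed.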

Results

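Transcript counts were taken from the skin of 3 mice before and after a UVB exposure, in 85 tissue segments of 5 compartments. PanCK-positive segments were selected for epithelial cells and CD45-positive segments for leukocytes. Both kinds were taken in the epidermis and the deep dermis, and CD45-positive segments in the adipose layer as well. Both epidermal groups at 0 h had 8 segments, all other groups of the epidermis and deep dermis had 6, and adipose had 3, 2 and 4 at 0, 6 and 24 h. Every group held 3 mice except adipose at 6 h, which held 2. Total counts per segment ranged from 37665 to 248825 in PanCK epidermis, from 10771 to 256121 in CD45 epidermis, from 16210 to 197481 in PanCK deep dermis, from 4244 to 84735 in CD45 deep dermis and from 28335 to 143225 in adipose. In PanCK epidermis the median total was 125896.5 at 0 h, 93783 at 6 h and 44540 at 24 h. Probes stand under their identifiers, since the deposited values do not pair them with genes.

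The series concerns inflammatory change in skin after ultraviolet light, and the comparisons over time ask which layers changed, when and in which direction. The labels name no unexposed skin at 6 h or 24 h. Effects of UVB therefore cannot be told apart from other changes over time, such as those of handling or biopsy. At 24 h, changes were most numerous in the PanCK epidermis, where 1279 of 6076 tested probes were called, and made up the largest share of tested probes in the CD45 epidermis, 52.0%. Of the tested probes, 22.6% were called in PanCK deep dermis, 9.46% in CD45 deep dermis and 2.38% in CD45 adipose. At 6 h, between 1 and 67 probes were called per compartment. These counts differ in tested probes and in depth, so they were not read as sizes of response.

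**Figure D1:**
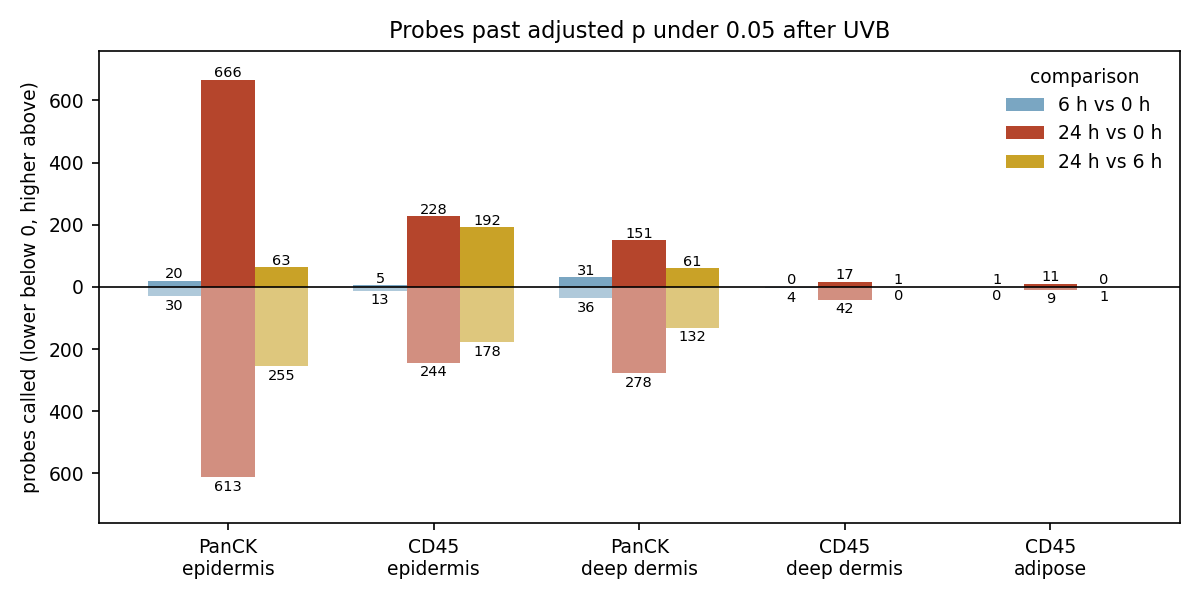
Number of probes called by edgeR's quasi-likelihood test in each compartment, on a linear axis, with higher probes above 0 and lower probes below; colours give the comparison of times. In PanCK epidermis, 666 probes were higher and 613 lower at 24 h than at 0 h, and 20 and 30 at 6 h.

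In the PanCK epidermis, UVB was followed at 24 h by both rises and falls, of similar number. Of the 1279 called probes, 666 were higher than at 0 h, by a median log2 fold change of 1.54, and 613 were lower, by a median of -1.33. At least 4-fold, 87 rose and 55 fell. Rises and falls lay at different abundances. Among tested probes above the median abundance 190 rose and 603 fell, and among those below it 476 rose and 10 fell. Both the filter and the abundance use the 24 h sums, so a scarce probe could be tested because it was high at 24 h. How much of the split this selection gives was not tested. By 24 h, 484 of the 666 risen probes exceeded 2 times the mean level of the floor probes, which was 18.8 CPM at 0 h and 32.9 CPM at 24 h. The balance of rises and falls moved with the scaling and the filter: 74 rose and 2712 fell with scaling to the floor probes, 203 and 1244 without the filter, 40 and 1498 on mean log values, 434 and 372 among probes above the floor, and 117 and 381 with DESeq2's test. Without mouse 208 the call count was 602 (128 higher, 474 lower), and without mouse 210 it was 373 (160 higher, 213 lower).

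The named falls were of abundant probes and were not called at 6 h. RTS0070155 stood at 5023 ± 1141 CPM (SD, n = 3) at 0 h, 3860 ± 1623 at 6 h and 288 ± 198 at 24 h, lower in 3 of 3 mice, with a log2 fold change of -4.02 (SE 0.37; adjusted p = 1.37e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). RTS0073541 went from 6530 ± 852 CPM at 0 h and 5881 ± 1335 at 6 h to 874 ± 309 at 24 h, again lower in 3 of 3 mice, by -2.82 (SE 0.27; adjusted p = 1.37e-07, same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). RTS0073610 rose early and stayed high: 56.8 ± 7.40 CPM at 0 h, 207 ± 29.7 at 6 h and 285 ± 88.1 at 24 h, higher in 3 of 3 mice at both times, by 1.97 at 6 h and 2.44 (SE 0.29) at 24 h (adjusted p = 3.46e-06 at 24 h, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). At 24 h against 0 h in PanCK epidermis, these 3 probes kept their direction and were called under all 12 alternatives; the 6 h change of RTS0073610 was not run under them. RTS0072263 rests on 1 mouse: its 24 h level ranged from 53.7 to 1580 CPM, with the highest value in mouse 219. Its log2 fold change was 4.50 (SE 0.62; adjusted p = 2.54e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; higher in 3 of 3 mice). Without mouse 219 its change was 1.72 with an adjusted p of 0.0628 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, within a range of 2.29e-05 to 0.0628 over its alternatives.

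**Figure D2:**
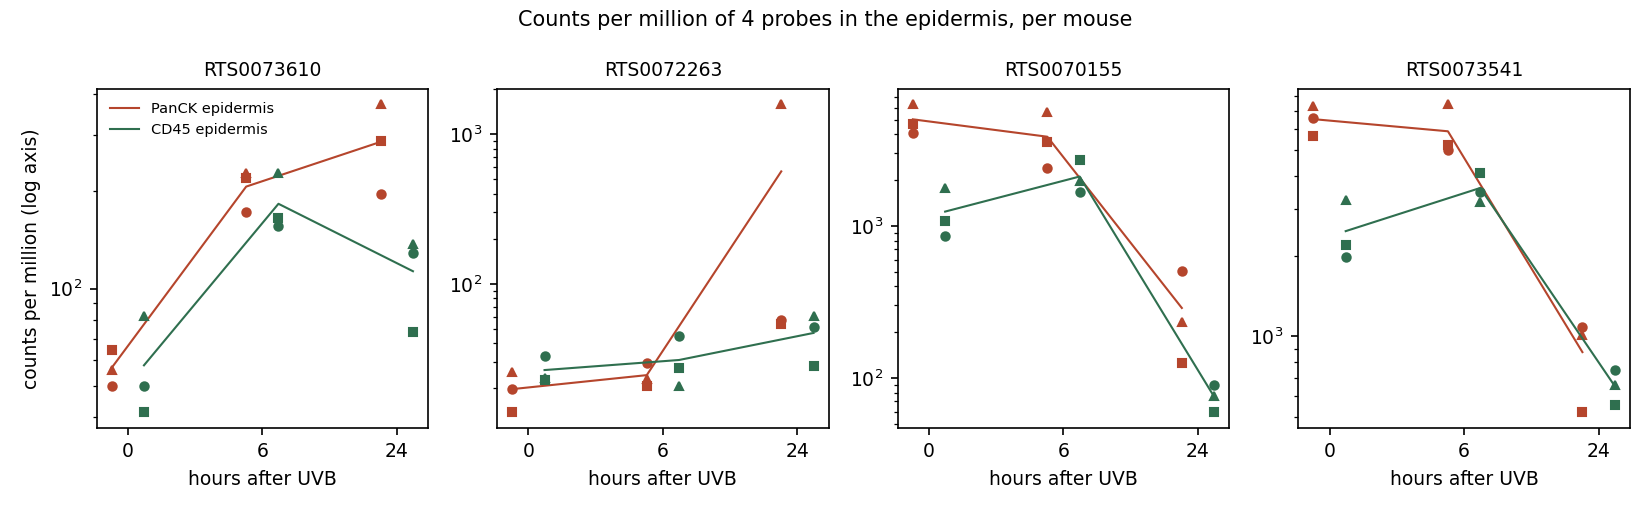
Levels in CPM (counts scaled to the total of their sum, log axis) of 4 probes in PanCK and CD45 epidermis at 0, 6 and 24 h; circles are mouse 208, squares mouse 210 and triangles mouse 219, and lines join the means; times are evenly spaced, not to scale. RTS0070155 and RTS0073541 were lower at 24 h in 3 of 3 mice in both kinds of segment. In PanCK epidermis the 24 h mean of RTS0072263 is set by mouse 219.

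At 6 h the PanCK epidermis had few calls, 20 higher and 30 lower of 6076 tested. From 6 h to 24 h, 318 probes changed, 63 upward and 255 downward. Scaling to the floor probes gave 421 calls at 6 h (18 higher, 403 lower) and 732 from 6 h to 24 h (16 higher, 716 lower), DESeq2's test gave 25 at 6 h, and limma on mean log values gave 4 and 754 (1 higher, 753 lower). Without mouse 208 or 210, the 6 h count was 19 or 5. Without mouse 210 or 219, the count from 6 h to 24 h was 8 or 124.

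Counts in the epidermis became spread more evenly over the probes by 24 h. In PanCK epidermis the 100 most abundant probes held 19.3% ± 2.25 (SD, n = 3) of counts at 0 h, 17.3% ± 1.52 at 6 h and 9.75% ± 0.92 at 24 h, lower in 3 of 3 mice. The 5000 floor probes went from 9.38% ± 1.04 to 16.5% ± 0.73. In CD45 epidermis the top share went from 13.2% ± 2.04 to 8.96% ± 0.76, lower in 3 of 3 mice. It went from 12.3% ± 0.72 to 11.3% ± 0.66 in PanCK deep dermis, from 11.5% ± 0.31 to 9.19% ± 0.79 in CD45 deep dermis (lower in 3 of 3 mice) and from 13.5% ± 2.07 to 11.8% ± 3.91 in adipose. With 3 mice, an exact two-sided permutation within mice cannot give a p below 0.25, so these shares are given as values with their spread.

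**Figure D3:**
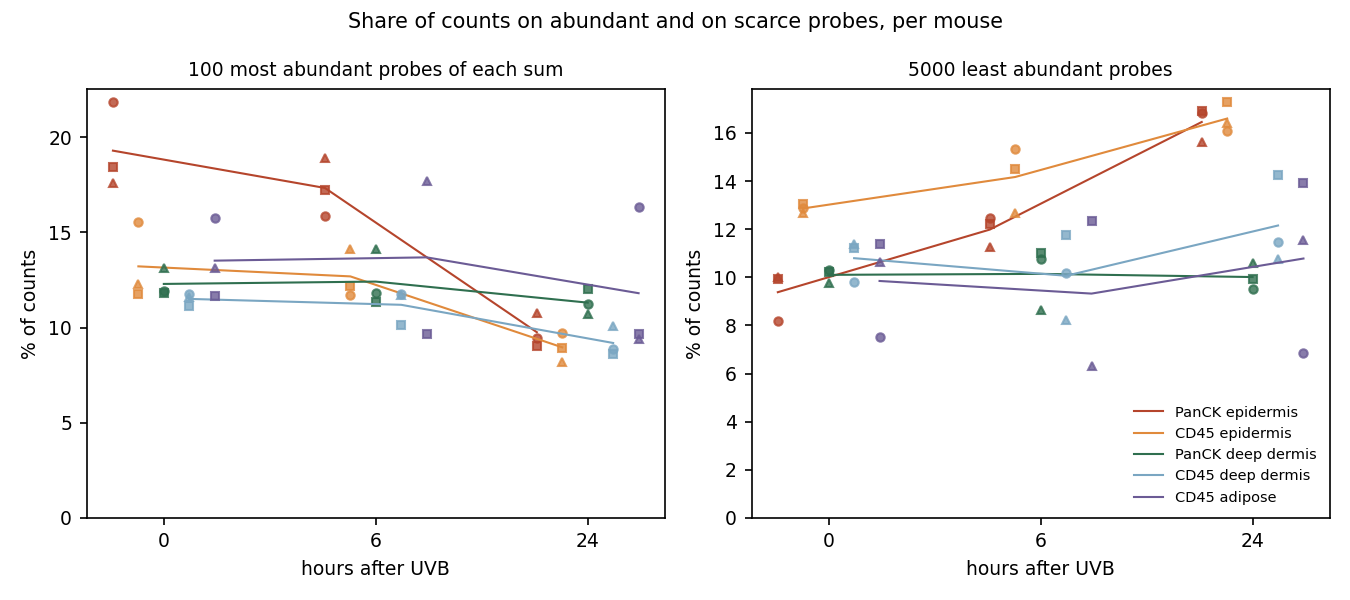
Percent of counts on the 100 most abundant probes of each sum (left) and on 5000 scarce probes chosen in deep dermis and adipose (right), at 0, 6 and 24 h; symbols are mice (circle 208, square 210, triangle 219) and lines join compartment means; times are evenly spaced, not to scale. In PanCK epidermis the top share was 19.3% at 0 h and 9.75% at 24 h.

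In the CD45 epidermis, 472 of 907 tested probes were called at 24 h, 228 higher and 244 lower. The median log2 fold change was 1.96 for the rises and -1.48 for the falls, and 109 rose against 55 that fell at least 4-fold; 14 rose at least 16-fold. RTS0070155 changed by -3.50 (adjusted p = 1.22e-06), RTS0073541 by -1.35 (adjusted p = 0.00111) and RTS0073610 by 1.51 (adjusted p = 0.00267), each in 3 of 3 mice (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Outside the epidermis none of the 4 named probes was called at 24 h against 0 h. RTS0073541 changed by -0.21 in PanCK deep dermis, -0.33 in CD45 deep dermis and 0.14 in adipose, and RTS0073610 by 0.50 in PanCK deep dermis; the other pairs of named probe and compartment were not tested. At 6 h, 5 probes were higher and 13 lower, and from 6 h to 24 h 192 were higher and 178 lower. Scaling to the floor probes gave 138 higher and 542 lower at 24 h against 0 h, and 64 and 406 at 24 h against 6 h; it moved the median of all tested probes by -0.97 at 24 h against 0 h, so which direction had the larger changes depends on the scaling. At 24 h against 0 h, 104 rose and 413 fell without the filter, and 92 and 282 on mean log values. Without mouse 210 the 24 h count was 312, without mouse 219 the 6 h count was 5, and from 6 h to 24 h the counts were 220 and 211 without mouse 210 and 219.

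Among probes tested in both kinds of epidermal segment, changes at 24 h were largely alike. Such probes made up 130 of the 666 rises and 355 of the 613 falls called in PanCK epidermis, so the others could not be compared. Of 869 probes tested in both, 119 rose in both where independent lists would share 31.4, and 196 fell in both where independent lists would share 96.4; 2 probes called lower in PanCK segments were called higher in CD45 segments. Across probes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.81. PanCK epidermis and PanCK deep dermis shared 13 rises (8.65 for independent lists) and 87 falls (57.1) among 1823 probes, with r of 0.205; 26 probes fell in the epidermis and rose in the deep dermis, and 3 did the reverse. The 13 shared rises did not pass Fisher's exact test (one-sided adjusted p = 0.0942 over 20 such tests, Benjamini-Hochberg). The 2 kinds of deep dermal segment shared 8 rises (0.958) and 19 falls (3.49) among 526 probes, with r of 0.694. CD45 segments of the epidermis and the deep dermis shared 10 rises (2.61) and 22 falls (8.45) among 509 probes, with r of 0.58. These lists come from the same biopsies, so part of the sharing can belong to the biopsies. In both kinds of epidermal segment counts also became spread more evenly at 24 h, which by itself could make their changes alike. RNA of PanCK areas within CD45 segments could do so as well. Neither was tested, so the likeness is not read as a common response of 2 cell types.

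**Figure D4:**
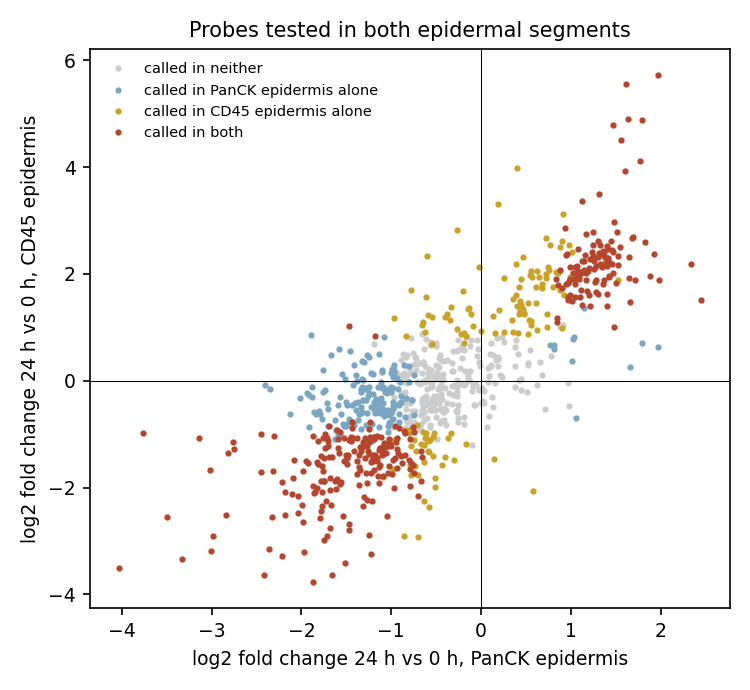
Log2 fold change from 0 h to 24 h of the 869 probes tested in both epidermal compartments, PanCK on the horizontal and CD45 on the vertical axis; colours mark where a probe was called. Pearson's r across probes is 0.81.

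In the PanCK deep dermis, falls outnumbered rises. At 24 h, 151 probes were higher and 278 lower, by medians of 1.41 and -1.89, and 28 rose against 121 that fell at least 4-fold. At 6 h, 31 were higher and 36 lower (42 and 20 with upper quartile scaling), and from 6 h to 24 h 61 were higher and 132 lower. Scaling to the floor probes gave 201 higher and 235 lower at 24 h against 0 h. Without mouse 210 the counts were 148 at 24 h against 0 h, 8 at 24 h against 6 h and 14 at 6 h, and the 6 h count was 104 without mouse 208 and 24 without mouse 219. With DESeq2's test, 264, 103 and 28 probes were called in these comparisons.

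In the CD45 deep dermis, 59 of 624 tested probes were called at 24 h, 17 higher and 42 lower, with medians of 2.32 and -2.02. At 6 h, 4 probes were called, all lower, out of 84 with an unadjusted p under 0.05. The 2 with the smallest p were RTS0068401 (log2 fold change -2.79, SE 0.44) and RTS0068409 (-2.72, SE 0.45), each with an adjusted p of 0.0202 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and lower in 3 of 3 mice. These 2 probes were chosen after their values were seen. At 6 h both were also called lower in PanCK epidermis (-2.13 and -1.83), CD45 epidermis (-2.01 and -1.57) and PanCK deep dermis (-1.90 and -1.62), while in adipose their values were -1.67 and -0.98 and were not called. In PanCK epidermis RTS0068401 stood at 1878 ± 528 CPM at 0 h, 401 ± 78.3 at 6 h and 217 ± 51.4 at 24 h. For both probes the deep dermal call was lost without mouse 208 (adjusted p = 0.139), without mouse 210 (adjusted p = 0.191) and on mean log values with limma (adjusted p = 0.374), where edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and the other alternatives ranged down to 0.00317. Without mouse 208 and 210 the 24 h count was 28 and 12, and the 6 h count was 0 in edgeR's test without either mouse, with 42 and 62 probes at an unadjusted p under 0.05, and 6 with DESeq2's test on all mice.

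From 6 h to 24 h, 1 probe was called in CD45 deep dermis, RTS0078277, chosen after its value was seen. It rose by 3.09 (SE 0.46; adjusted p = 0.0144, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), in 3 of 3 mice, from 22 counts of 208126 to 159 counts of 228347, a ratio of 6.59 (95% exact interval 4.20 to 10.8). In CD45 epidermis it went from 29.5 ± 11.2 CPM at 0 h to 622 ± 153 at 24 h, and in PanCK epidermis from 31.4 ± 17.2 to 101 ± 53.2. In PanCK deep dermis, where it was not tested, it stood at 83.8 ± 37.3 CPM at 6 h and 71.2 ± 22.1 at 24 h, lower in 2 of 3 mice. The deep dermal call was lost without mouse 208 (adjusted p = 0.0679), without mouse 210 (adjusted p = 0.304), without the filter (adjusted p = 0.121) and with limma (adjusted p = 0.839), with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment and the other alternatives ranging down to 0.00197.

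In the CD45 adipose layer few probes changed. At 24 h, 11 were higher and 9 lower than at 0 h, out of 93 with an unadjusted p under 0.05. RTS0067580, chosen after its values were seen, was the call at 6 h and also the call from 6 h to 24 h. Its counts were 5 of 142709 at 0 h, 57 of 87487 at 6 h and 5 of 260325 at 24 h, a ratio of 18.6 from 0 h to 6 h (95% exact interval 7.52 to 59.5; adjusted p = 0.00399) and of 0.0295 from 6 h to 24 h (0.00922 to 0.0729; adjusted p = 0.000296), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was higher at 6 h in 2 of 2 mice. The 6 h call was lost without mouse 208 (adjusted p = 0.174) or mouse 210 (0.96), with DESeq2's test (0.122) and with limma (0.981), and the call from 6 h to 24 h without mouse 208 (0.0553) or mouse 210 (0.947) and with limma (0.43), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment where no other tool is named. Over the alternatives, the adjusted p from edgeR's quasi-likelihood test (or the named tool) with Benjamini-Hochberg adjustment ranged from 9.94e-08 to 0.981 at 6 h and from 4.45e-13 to 0.947 from 6 h to 24 h. Without mouse 208, 210 and 219, edgeR called 0, 9 and 58 probes at 24 h against 0 h, 0, 6 and 25 at 6 h, and 0, 8 and 30 from 6 h to 24 h, the counts of 0 coming with 48, 16 and 51 probes at an unadjusted p under 0.05. Without the block no probe was called at 24 h against 0 h (count 0 in edgeR's test, 70 at an unadjusted p under 0.05), and DESeq2's test with the block called 5.

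In the epidermis and deep dermis, most probes called at 6 h were called in the same direction at 24 h, except for the rises in PanCK epidermis. There 10 of 20 rises and 28 of 30 falls were called again at 24 h, where independent lists would share 2.19 and 3.03. In CD45 epidermis 5 of 5 rises and 12 of 13 falls were called again (1.26 and 3.50), in PanCK deep dermis 23 of 31 and 31 of 36 (2.47 and 5.27), and in CD45 deep dermis 3 of 4 falls (0.269). None was called in opposite directions at 6 h and 24 h in these 4 compartments (count 0, edgeR's test). Across probes, the log2 fold changes at 6 h and 24 h correlated with r of 0.642, 0.447, 0.663, 0.736 and 0.374 in PanCK epidermis, CD45 epidermis, PanCK deep dermis, CD45 deep dermis and adipose. Unchanged groups simulated against the same controls gave r of 0.35, 0.455, 0.514, 0.514 and 0.439. The covariances were 0.304, 0.423, 0.454, 0.522 and 0.172 against simulated ones of 0.0481, 0.0637, 0.0788, 0.109 and 0.105. In CD45 epidermis and adipose the observed r was no higher than that of unchanged groups, while the covariance was higher in every compartment. The value of r also depends on the spread of the changes, which differs between real and unchanged groups. A low r therefore does not speak against a shared change. Both times share the 0 h sums, and the simulated unchanged groups shared at most 1 call. Unchanged groups have few calls to share, so this number does not show how much the shared sums add to the overlap of real calls. The overlaps for independent lists leave the shared sums out as well.

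Time courses differed between compartments. PanCK epidermis and PanCK deep dermis differed in 379 of 4268 tested probes, of which 160 had the higher 24 h change in the epidermis and 219 the lower. CD45 segments of the epidermis and the deep dermis differed in 146 of 1287 probes, with 97 higher and 49 lower in the epidermis. In the epidermis, CD45 and PanCK segments differed in 82 of 2936 probes, with 22 higher and 60 lower in the CD45 segments. Scaling to the floor probes turned or widened these splits: 37 higher and 1270 lower for the PanCK pair, 20 and 191 for the CD45 pair, and 78 and 37 within the epidermis. Upper quartile scaling gave 59 higher and 64 lower for the CD45 pair. The balance of directions therefore depends on the scaling. Tested at 24 h alone, 548, 144 and 92 probes differed, and at 6 h alone 3, 2 and 1. Among the probes called over both times, the median absolute difference was 0.71, 0.76 and 0.35 at 6 h against 2.12, 2.05 and 1.67 at 24 h. Without mouse 208, 210 and 219 the counts were 195, 55 and 378 for the PanCK pair, 87, 67 and 19 for the CD45 pair and 83, 26 and 38 within the epidermis.

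Before UVB, compartments differed in 121 to 412 of 1709 tested probes. In the epidermis 154 probes were higher and 129 lower in CD45 than in PanCK segments, and at least 4-fold 71 were higher and 2 lower. In the deep dermis 150 were higher and 110 lower in CD45 segments, with 97 and 47 at least 4-fold. CD45-positive segments shared their differences from PanCK-positive ones across layers, with 83 higher in both layers (13.5 for independent lists) and 33 lower in both (8.30). Against the epidermis, the deep dermis had 198 higher and 214 lower probes in PanCK segments, and 71 higher and 55 lower in CD45 segments (50 and 73 with upper quartile scaling). Adipose against deep dermis, both CD45, gave 46 higher and 75 lower, and falls dominated the large differences, with 66 lower and 7 higher at least 4-fold and 20 lower at least 16-fold. On mean log values with limma the directions turned in the deep dermis (30 higher and 152 lower in CD45 segments), in adipose (118 higher and 37 lower) and for CD45 deep dermis against epidermis (4 higher and 27 lower). The same fit gave 15 higher and 86 lower for PanCK deep dermis against epidermis, and called 10 probes within the epidermis, 5 in each direction. Except within the epidermis, more probes were higher on the side with the larger median total per segment. These medians were 125896.5 in PanCK epidermis, 49387 in CD45 epidermis, 52470.5 in PanCK deep dermis, 34350 in CD45 deep dermis and 53489 in adipose. Whether depth turned the directions was not tested. Without mouse 210 and 219 the counts were 89 and 80 for CD45 against PanCK in the epidermis, and 207 and 248 for PanCK deep dermis against epidermis. Without mouse 208, 210 and 219 they were 166, 123 and 107 for CD45 against PanCK in the deep dermis, and 61, 44 and 40 for CD45 deep dermis against epidermis, and without mouse 208 and 219 they were 33 and 25 for adipose against deep dermis.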

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

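The tests of a flat background, the reassignment of times within each mouse, and the spread over mice used to read background and depth were chosen after the result was seen; the other tests of this part were written down before their results, on patterns found in these data.

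In 4 of 39 tests of a group for a sample far from the others, 1 segment stood apart. Chance would pick out about 1 in 20 groups if values were independent. Here segments of the same mice were compared, by 3 measures of the same segments, so this rate is no firm reference. In PanCK epidermis at 6 h a segment of mouse 210 held 199929 counts, and the nearest held 106077. In PanCK deep dermis at 6 h a segment of mouse 210 held 197481 counts, and the nearest held 66144. In PanCK epidermis at 24 h a segment of mouse 219 had 12.5% of its counts on its 100 most abundant probes (95% Wilson interval 12.2 to 12.8%), and the nearest had 9.91%. In CD45 deep dermis at 24 h a segment of mouse 219 had 11.8% (11.4 to 12.3%), and the nearest had 9.43%. The no template control, a well with no tissue, held 19 counts on 14 probes out of 12302 aligned reads, where the lowest tissue segment held 4244 counts.

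Time courses differed between PanCK epidermis and PanCK deep dermis in 379 probes, between CD45 epidermis and CD45 deep dermis in 146, and between CD45 and PanCK epidermis in 82, by a test of the difference itself. In 100 splits that reassigned the 3 times among the 9 biopsies, the real one included, 1 split, the real one, was as large in each case, and the highest other counts were 243, 97 and 76. Most of these splits do not keep each mouse at every time. All 36 splits that do were therefore run as well: 1 of 36, the real one, was as large in each case. The highest other counts were 186, 107 and 71. A share of 1 of 36 is the smallest this test can give, and it was not adjusted for the 3 pairs. It argues against chance but does not exclude it. The margin is small for 82 against 76 and 71.

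For the other comparisons of 3 sums with 3 sums, 10 splits exist, too few for a share under 0.05. In PanCK epidermis the real counts were 50, 1279 and 318 (6 h against 0 h, 24 h against 0 h and 24 h against 6 h) and the highest other 9, 4 and 13. In CD45 epidermis they were 18, 472 and 370, and the highest other split gave 0, 0 and 0. In PanCK deep dermis 67, 429 and 193 stood against 1, 0 and 0, and in CD45 deep dermis 4, 59 and 1 against 1, 0 and 4. In adipose at 24 h against 0 h, 20 stood against 5. At 0 h, the CD45 against PanCK counts were 283 in the epidermis and 260 in the deep dermis, those of the deep dermis against the epidermis were 412 for PanCK and 126 for CD45, each against 0, and adipose against deep dermis gave 121 against 3. The count of splits as large was 1, the real one, except in CD45 deep dermis from 6 h to 24 h, where it was 4. Of each 10 splits, 4 part every mouse's pair of sums as the real one does; in adipose at 24 h the highest other split was of this kind.

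Epidermal counts were spread more evenly over the probes at 24 h. In PanCK epidermis 476 rises lay below the median abundance of the 6076 tested probes and 190 above it, a split that the filter may in part give. In CD45 epidermis 103 lay below that of its 907 tested probes and 125 above it. All 907 also passed the filter that keeps probes above the floor level, so rises of scarcer probes could not be seen there. The 2 splits are therefore not compared. In CD45 epidermis, subtracting the level of the floor probes left 17.6% of the fall of the top-100 share, but 85.7%, -145% and 33.1% by mouse; depth gave -1.08% ± 7.76 (SE) of the rise of the floor share, with the 24 h segments shallower in 1 of 3 mice, which argues against shallower segments as the main cause. In PanCK epidermis, 27.8% of the fall was left (31.1%, 33.2% and 14.1% by mouse) and depth gave 22.3% ± 10.0 (SE) of the rise, so depth stays open there, and a flat background that may have grown relative to specific counts stays open in both compartments. A true fall of abundant epidermal transcripts after UVB, the explanation the design names, also stays open and untested, since a share cannot tell a lost signal from added background. The floor probes are not known to be negative controls, which keeps the background reading a hypothesis.

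CD45 deep dermis had 59 calls at 24 h, fewer than CD45 epidermis (472) or PanCK deep dermis (429). Thinning argues against lower depth as the whole cause: at the totals of CD45 deep dermis, CD45 epidermis still gave a median of 285.5 calls (258 to 314 in 20 thinnings) and PanCK deep dermis 229 (207 to 245). In CD45 epidermis 2 sums were already at or below those totals and stayed at full depth. The time courses of the CD45 compartments differed in 146 probes, and over all tested probes the median absolute log2 fold change was 0.52 in CD45 deep dermis against 0.96 and 0.56, with a median standard error of 0.42 against 0.37 and 0.38. A smaller response and a larger error may both add to the difference; how much each adds was not tested.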

How the results depend on the processing

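Scaling to the floor probes and the filter that keeps probes above their level were chosen after the results were seen; the other alternatives were not. Counts of calls are given as in the report, for 23 comparisons. The number of counts that stayed within 1.5 times their value was 22 with DESeq2's size factors, 21 with upper quartile scaling, 13 with no filter, 14 with DESeq2's test, 5 on mean log values, 23 without shallow segments, and 9, 2 and 9 without mouse 208, 210 and 219. It was 22 with probes above the floor, 13 of 15 without the block and 10 of 18 with scaling to the floor probes. Except where a construction is named, the cause was not tested. In simulated counts at the real depths, 12% of 2-fold changes were called in PanCK epidermis at 24 h and 22 to 33% in the other compartments, so most were missed. Only 200 probes were changed there. The Benjamini-Hochberg adjustment is less strict where more probes change, as in PanCK epidermis with 1279 calls at 24 h. These shares therefore need not hold for the real comparisons. The gene list tests and their alternatives were not run, since the deposited values do not pair probes with genes.

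With DESeq2's size factors CD45 deep dermis at 6 h gave 7. With upper quartile scaling it gave 8 (2 higher, 6 lower), and adipose from 6 h to 24 h gave 2 (1 and 1). In the same scaling CD45 against PanCK epidermis at 0 h parted into 175 higher and 95 lower. Median shifts of all probes over 0.1 log2 were 0.15 with DESeq2's size factors (CD45 epidermis at 24 h), and with upper quartile scaling 0.12 (PanCK deep dermis at 6 h), 0.11 (CD45 against PanCK epidermis) -0.16 (CD45 deep dermis against epidermis) and -0.15 (24 h difference of the CD45 time courses, which parted into 59 higher and 64 lower).

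Without the filter, which tests more probes, counts were 246 for CD45 deep dermis against epidermis at 0 h, 88 and 612 for the CD45 and PanCK time courses of epidermis against deep dermis, 24, 34 and 0 in CD45 deep dermis (6 h against 0 h, 24 h against 0 h and 24 h against 6 h), 23 and 21 in adipose at 6 h and from 6 h to 24 h, 186 (36 higher, 150 lower) in CD45 epidermis from 6 h to 24 h and 110 in PanCK deep dermis at 6 h.

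With DESeq2's test, counts were 171 for the PanCK time courses of epidermis against deep dermis, 25 and 498 (117 higher, 381 lower) in PanCK epidermis at 6 h and 24 h, 28, 264 and 103 in PanCK deep dermis (same order of comparisons), 10 in CD45 epidermis at 6 h, and 0 and 5 in adipose at 6 h and 24 h. On mean log values with limma, counts at 0 h were 31 for CD45 deep dermis against epidermis, 10 for CD45 against PanCK epidermis and 101 for PanCK deep dermis against epidermis. Time courses differed in 26 probes for CD45 epidermis against deep dermis and 7 for CD45 against PanCK epidermis. Over time, limma gave 4 in PanCK epidermis at 6 h and 754 (1 higher, 753 lower) from 6 h to 24 h, 9 and 216 in CD45 epidermis, 5, 125 and 13 in PanCK deep dermis, 0, 4 and 0 in CD45 deep dermis, and 0, 0 and 0 in adipose. In PanCK epidermis at 24 h limma gave 1538, of which 40 were higher. In simulated counts of that comparison, 37% of 4-fold changes were called on mean log values and 71% with edgeR.

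Without the replicate block, adipose at 24 h gave 0 in place of 20, and CD45 deep dermis at 6 h gave 9 in place of 4; it moved no other count past 1.5 times and kept the 9 calls of named probes that were run under it. With probes above the floor, which tests fewer, PanCK epidermis at 24 h gave 806 (434 higher, 372 lower).

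With scaling to the floor probes, PanCK epidermis gave 421 (18 higher, 403 lower) at 6 h, 2786 (74 and 2712) at 24 h and 732 (16 and 716) from 6 h to 24 h. Adipose gave 2 at 6 h and 2 at 24 h, and CD45 deep dermis 15 (9 and 6) at 6 h and 25 (1 and 24) from 6 h to 24 h. CD45 epidermis parted into 4 higher and 19 lower at 6 h. The PanCK time courses of epidermis against deep dermis differed in 1307 probes (37 higher and 1270 lower in the epidermis at 24 h), the CD45 ones in 211 (20 and 191), and those of CD45 against PanCK epidermis in 115 (78 and 37), moving the median 24 h difference by -1.20, -0.95 and 0.51. Under this scaling the median of all probes moved by -0.43, -0.91 and -0.48 in PanCK epidermis, -0.14, -0.97 and -0.83 in CD45 epidermis, 0.19 and 0.11 in PanCK deep dermis (24 h against 0 h and 6 h), 0.42, -0.12 and -0.53 in CD45 deep dermis, and 0.64, -0.18 and -0.81 in adipose.

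With each mouse left out in turn, which leaves fewer samples, counts at 0 h ranged from 40 to 61 for CD45 deep dermis against epidermis, 107 to 166 for CD45 against PanCK deep dermis, 80 to 213 for CD45 against PanCK epidermis, 207 to 320 for PanCK deep dermis against epidermis and 25 to 86 for adipose against deep dermis. Time course differences ranged from 19 to 87 for CD45 epidermis against deep dermis, 26 to 83 for CD45 against PanCK epidermis and 55 to 378 for PanCK epidermis against deep dermis. For 6 h against 0 h, 24 h against 0 h and 24 h against 6 h, the ranges were 5 to 37, 373 to 958 and 8 to 232 in PanCK epidermis, 5 to 27, 312 to 547 and 211 to 390 in CD45 epidermis, 14 to 104, 148 to 483 and 8 to 204 in PanCK deep dermis, 0 to 6, 12 to 41 and 0 to 1 in CD45 deep dermis, and 0 to 25, 0 to 58 and 0 to 30 in adipose. Where adipose at 6 h is left with 1 mouse, that mouse is assumed to vary like the other groups. The counts of 0 named in these paragraphs, 15 in all from edgeR, DESeq2 or limma, had 16 to 552 probes at an unadjusted p under 0.05.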

Other observations

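The lists and the pairing of neighbouring identifiers were chosen after patterns in these data were noticed, and what each test would show was written down before its result; the reading of neighbouring identifiers over the range of sums was chosen after the result was seen.

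Probes that marked the epidermis before UVB lost share in CD45 epidermis segments. Of the 214 probes higher in PanCK epidermis than in PanCK deep dermis at 0 h, 129 were tested in CD45 epidermis at 24 h; 80 were called lower and 3 higher. Their median log2 fold change was -1.26, where abundance-matched random lists had a median of -0.12, at percentile 0 of 10000 such lists, and it lay above the matched probes in 0 of 3 mice. This could mean that less epithelial RNA reached the CD45 areas at 24 h, or that keratinocytes themselves lowered these transcripts. PanCK epidermis segments also changed, so the test cannot separate these. The list and the 0 h CD45 epidermis sums come from the same biopsies. A high level that both shared by chance at 0 h could therefore also give a fall, and the random lists were matched on abundance alone. A flat background that may have grown relative to specific counts stays open here too.

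Probes that set CD45 areas apart from PanCK areas in the deep dermis before UVB went both ways in the epidermis. Without gene names they cannot be read as transcripts of leukocytes. Of the 150 probes higher in CD45 than in PanCK segments of the deep dermis at 0 h, 73 were tested in each kind of epidermal segment. In CD45 epidermis 16 were called higher and 20 lower at 24 h, with a median of -0.20 at percentile 54.6 of 10000 abundance-matched random lists. In PanCK epidermis 7 were higher and 20 lower, with a median of -0.41 at percentile 56.4. These medians lie amid those of the random lists, above the matched probes in 1 of 3 and 2 of 3 mice, over members that went both ways. The medians therefore do not decide whether transcripts of CD45 areas gain share in the epidermis by 24 h. The bound written down beforehand would have counted them against it. The list comes from the resting deep dermis, so it may lack transcripts of cells that would enter the epidermis.

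Probes with consecutive identifiers changed alike. The 24 h changes of consecutive tested identifiers correlated with r of 0.223 in PanCK epidermis (2347 pairs), 0.491 in CD45 epidermis (171), 0.431 in PanCK deep dermis (430), 0.222 in CD45 deep dermis (122) and 0.0384 in adipose (149). One-sided permutation p-values over 10000 permutations were 1e-04 in the first 3, the smallest they can give, 0.0066 and 0.31, and 0.00017, 0.00017, 0.00017, 0.0082 and 0.31 after Benjamini-Hochberg adjustment of these permutation values over the 5 tests. If neighbours shared measurement noise, deviations of mice from their group mean would correlate as well; they did so at 14.5%, 27.7% and 24.7% of the r of changes in PanCK epidermis, CD45 epidermis and PanCK deep dermis. The highest sum gave 49.0%, 42.9% and 35.8%, under the 50% that noise as the whole cause was written down to need, which argues against it there, though narrowly in PanCK epidermis. The stricter bound written down beforehand, under 25%, was not met over these ranges. In CD45 deep dermis the value was 74.5% and the highest sum 150%, so noise stays open; in adipose, at 422%, there was no correlation of changes to explain. A candidate explanation is that neighbouring identifiers often belong to related genes, which cannot be examined without gene names.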
